A study of Mus musculus with 2 samples.

How the data were processed

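The data are 2 one-colour (Cy3) Agilent arrays, 1 of control CMT93 cells and 1 of LPS-treated cells, assigned by the sample titles. Per the labels' protocols, cells were grown in DMEM, total RNA was extracted with Trizol, and labelled RNA was made with T7 RNA polymerase. The treatment text is the same on both samples, so the dose and time were taken to apply to the LPS sample alone.

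The deposited values are spot intensity values from Agilent Feature Extraction 10.10.1.1, per the file headers. The processed intensity was background-subtracted and detrended over the slide, per the file headers. Probes are 60 bases long, and their coordinates fit the mouse build mm9 that the headers name.

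From there, control spots and flagged spots were left out (223 spots flagged on either array). The processed intensity was put on the log2 scale, and the 75th percentile of the non-control spots was subtracted on each array. Most spots were above background on each array, so all non-control spots set the percentile. Spots of one probe were averaged, and a gene took the value of its brightest probe. A gene was called measured where that probe was well above background on both arrays. Symbols were updated through accessions in a RefSeq table of GRCm38.p6, which matched 28026 of 55677 probes (50.3%) and changed 1651 symbols. Other probes kept the name in the files. No coordinate of that table was used, and whether a probe lies in an exon or a UTR was not analysed here.

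With 1 array per group no test was run. Genes were described by size, at 2-fold and also at 1.5-fold and 4-fold. Lists with at least 5 measured members were set against 10000 random lists drawn from 20 bins of brightness. The error given is the SD over spots of 399 probes printed 10 times. It covers the slide only, and the number of arrays limits the precision.

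The 37 gene lists, the alternatives and the rule for named genes were fixed before the data were examined, except for 2 alternatives, the block correction and the random lists matched on GC. The rule takes the LPS receptor genes Tlr4, Ly96, Cd14, Lbp and Myd88. It adds the 12 largest differences in each direction among genes at or above the median brightness whose probes share a sign, leaving out names that are only clones, gene models or accessions. It also takes the 2 highest and 2 lowest members of each list, and the 5 largest bounds in each direction among genes above background on 1 array. Genes outside it are said to be chosen after their values were seen. One gene that the rule takes is not reported here.

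The alternatives were normexp background correction with an offset of 50, background-subtracted signal floored at 1, quantile normalization, cyclic loess with a span of 0.7, median centring, the 75th percentile of detected probes, spike-in scaling on 7 probes, the median over probes, other filters, and other random lists. They used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

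The size rule and the random lists were tested on simulated data for LPS against control, over 20380 genes with noise of the size seen between spots. Of 50 genes set to each log2 difference, 0 were called at 0.5 and 50 at 1.5, 50 at 2 and 50 at 3. None of 20180 unchanged genes was called, which the setting fixed in advance, since the noise SD was at most 0.20 against a log2 threshold of 1. Among dim replicated probes above the floor the SD reached 0.50. The simulation thus does not show that noise gave no 2-fold genes. Of 200 lists with no difference, 9 lay outside the central 95%, and 50 of 50 lists with most members raised by 0.5 lay above. The first count was near fixed in advance, since these lists came from the same independent genes as the random lists. The real log2 differences had an SD of 0.38 over genes, above the simulated noise, so the 50 of 50 does not carry over. The simulation holds no spread between cultures.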

Results

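Total RNA of CMT93 cells was measured on 2 one-colour Agilent mouse arrays. CMT93 is an established mouse carcinoma line of the large bowel, from the rectum of a C57BL/ICRF animal. One array held control cells and the other held cells given lipopolysaccharide (LPS), the outer membrane glycolipid of Gram-negative bacteria, at 3 µg/mL for 24 h. The comparison asks which transcripts differ in level between LPS-treated and control cells. Each group had 1 array, so no difference below has a replicate check, no test between the groups was possible, and the number of arrays limits the precision. Both arrays lay on 1 slide and were read in 1 scan. Of 59305 non-control spots, 33091 (55.8%) were well above background on the control array and 32448 (54.7%) on the LPS array, and no spot was saturated. In all, 20380 genes, counted by symbol or array name, were measured on both arrays. Of these, 13097 had a gene name. The others had only a clone, gene-model, accession or probe name, so a gene can be counted more than once.

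The largest difference by the naming rule among genes measured on both arrays was that of Lcn2, which encodes the iron-sequestering protein lipocalin 2, at 613-fold, a log2 difference of 9.26 that was 8.58 with normexp. The neutrophil chemokine gene Cxcl5 was 132-fold higher and the acute-phase gene Saa1 was 60.9-fold higher. C3, which encodes the central component of complement, was higher by 6.49 on the log2 scale, and by 4.67 with normexp and 4.84 with floored signal. Among genes at or above the median brightness, those that were lower differed less. Of these, Lgals4, which encodes the intestinal lectin galectin 4, was 2.74-fold lower. Kit, which encodes the stem cell factor receptor, was 2.45-fold lower. Dimmer genes went further, with 17 at least 4-fold lower, though only 1 with normexp.

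In total, 297 genes were at least 2-fold higher on the LPS array and 116 were at least 2-fold lower, together 2.03% of the measured genes. Of those with a gene name, 208 were at least 2-fold higher and 80 were lower. At least 4-fold differences were seen for 78 higher and 17 lower genes, and at least 1.5-fold differences for 731 and 541. The higher genes made up 71.9% of the 2-fold genes, and 82.1% with normexp background correction, which left 170 higher and 37 lower genes. Among genes at or above the median brightness, 94 were at least 2-fold higher and 15 were lower, so 203 of the 297 higher genes and 101 of the 116 lower genes were dim. Of 81 genes at least 2-fold different that had another measured probe, the other probes differed at least 1.41-fold the same way for 43, by less for 37 and the opposite way for 1.

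**Figure D1:**
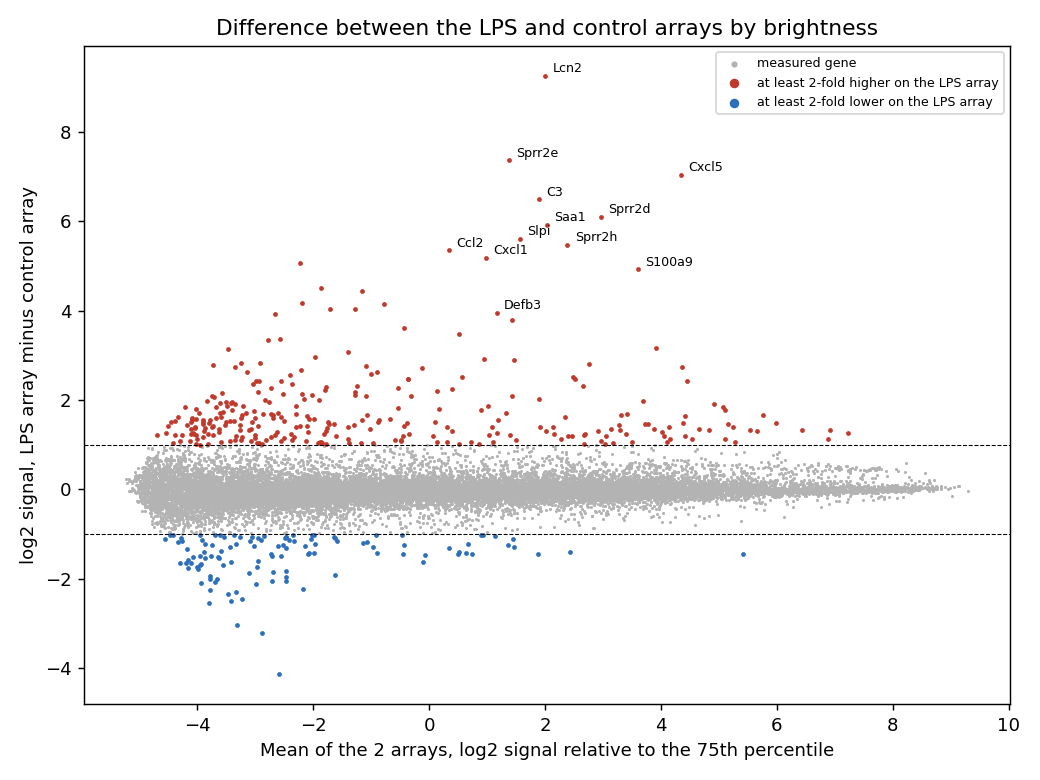
Each point is 1 of the 20380 measured genes, with the mean log2 signal of both arrays on the x axis and the log2 difference, LPS minus control, on the y axis; dashed lines mark 2-fold. The 12 labelled genes are the largest positive differences among the brighter genes, from 3.95 (Defb3) to 9.26 (Lcn2), and most genes past 2-fold either way lie at low brightness.

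The only error these arrays give is the spread between repeated spots of one probe, which covers the slide and not the cultures. Over 257 probes printed 10 times and above the background floor, the SD of the log2 difference had a median of 0.05. It was 0.03 for the brightest probes and 0.20 for the dimmest ones above the floor. The error after each ± below is this SD for probes of similar brightness.

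Lcn2 stood at a log2 difference of 9.26 ± 0.20, with its probe on chromosome 2 at 32240199 to 32240258 (mm9). Sprr2e, Sprr2d and Sprr2h, which encode small proline-rich proteins of the cornified envelope, stood at 7.37 ± 0.20, 6.10 ± 0.07 and 5.48 ± 0.07. Probes of the Sprr2 genes, and those of the Lgals, Scgb and Saa genes below, were not set against the transcripts of related genes, so signal shared between relatives is not excluded. Among chemokine genes, Cxcl5 stood at 7.04 ± 0.05, the monocyte attractant gene Ccl2 at 5.36 ± 0.20 and Cxcl1 at 5.18 ± 0.07. C3 stood at 6.49 ± 0.07 on its brightest probe and at 4.85 on its other one. Saa1, the protease inhibitor gene Slpi, the calprotectin subunit gene S100a9 and the beta-defensin gene Defb3 stood at 5.93 ± 0.07, 5.61 ± 0.07, 4.93 ± 0.05 and 3.95 ± 0.07.

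The 12 lower genes picked by the same rule lay between -1.45 and -1.05. Lgals4 was at -1.45 ± 0.03, with its 3 probes between -1.45 and -1.41, and its close relative Lgals6 was at -1.41 ± 0.05. The Lgals6 probe has no mm9 position, and Lgals4 signal on it is not excluded, so these may not be separate measurements. The pancreatic colipase gene Clps was at -1.45 ± 0.05, the secretoglobin genes Scgb2b2 and Scgb2b20 at -1.44 ± 0.07 and -1.24 ± 0.05, and Kit at -1.29 ± 0.05. For Scgb2b20 a further probe gave only -0.31. Slc4a11, Sema7a, Cd200r2, Prss12, Homer2 and Sertad4 made up the rest, at -1.44, -1.43, -1.31, -1.21, -1.10 and -1.05.

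Another 646 genes were well above background on the LPS array only, and 928 on the control array only. By the bounds described below, 291 of the 646 and 174 of the 928 were at least 2-fold higher on that array. Most genes in either direction thus had a bound under 2-fold. Saa3, an acute-phase serum amyloid A gene, was at least 4926-fold higher on the LPS array, and S100a8, the partner of S100a9, at least 21.3-fold higher. The anion exchanger gene Slc26a4 was at least 13.8-fold higher, and Them5 and Ntsr2 at least 10.7-fold and 10.6-fold. On the control array, Olfr472 and Olfr69, olfactory receptor genes, were at least 13.9-fold and 11.4-fold higher, followed by Foxe1, Prg4 and Platr21 at 9.67-fold, 7.71-fold and 7.47-fold or more. Each bound sets the brighter array against the higher of the dim probe's own signal and the lowest signal among probes well above background on the dim array. The bounds depend on the background correction: with normexp each was smaller, and the log2 bounds were 9.81 for Saa3 and 2.48 for S100a8, against 12.27 and 4.41.

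The receptor complex for LPS itself was measured. Tlr4, the LPS receptor gene, was at 0.33 ± 0.07, its co-receptor gene Ly96 at 0.07 ± 0.05 and the adaptor gene Myd88 at 0.42 ± 0.05, all under 2-fold. Cd14 and Lbp, whose products deliver LPS to the receptor, were 2.02-fold and 2.49-fold higher, at 1.02 ± 0.03 and 1.31 ± 0.05, with Cd14 at the edge of 2-fold with quantile normalization. Of 30 measured genes of LPS recognition and Toll-like receptor signalling, 4 were at least 2-fold higher, none was 2-fold lower and 26 were neither, with a median of 0.12. Ikbke, a kinase gene of the pathway, was highest at 1.59 ± 0.20, and Sigirr, which encodes a negative regulator of the receptors, was lowest at -0.29 ± 0.03. Tlr2, chosen after its value was seen, was above background on the LPS array only and at least 2.24-fold higher. Another 6 members of the list were above background on neither array.

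Targets and feedback genes of NF-kB, the transcription factor that Toll-like receptors activate, were higher as a group. Of 23 measured members, 10 were at least 2-fold higher, none was 2-fold lower and 13 were neither, with a median of 0.78. Zc3h12a, which encodes an RNase that degrades cytokine transcripts, was at 4.19 ± 0.20 (2.81 with normexp) and Tnip3 at 3.62 ± 0.20, while Peli1 and Gadd45b were at -0.16 ± 0.03 and 0.03 ± 0.03. Among 14 measured chemokine genes, 8 were at least 2-fold higher, none was lower and 6 were neither, with a median of 1.13. Over the 15 alternatives that median ranged from 0.62 to 3.14. Cxcl17 and Ccl6 were lowest at -0.33 each. A further 4 chemokine genes, named after their values were seen, were above background on the LPS array only. Of these, Cxcl2 and Ccl7 were at least 10.4-fold and 8.97-fold higher, and Ccl17 and Cxcl10 at least 1.98-fold and 1.68-fold. Cxcl15, also named after its value was seen, was above background on the control array only and at least 2.62-fold lower. The other 14 chemokine genes on the list were above background on neither array.

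Of 21 measured cytokine and growth factor genes, 6 were at least 2-fold higher, none was lower and 15 were neither, with a median of 0.34. This median lay between 0.13 and 0.86 over the 15 alternatives. Csf3, the granulocyte colony-stimulating factor gene, was at 4.15 ± 0.20 and Tnf at 4.04 ± 0.20 (3.39 and 3.10 with normexp), and the lowest was Il18 at -0.67 ± 0.03. Of the cytokine list, 13 genes were above background on neither array. Antimicrobial and acute-phase genes had a median of 1.40, and of 0.38 without the background filter, with 11 of 20 measured members at least 2-fold higher, none lower and 9 neither. Ang4 and Pigr, at -0.21 ± 0.20 and -0.05 ± 0.03, were its lowest measured members. Bpi and Sprr2a1, chosen after their values were seen, were above background on the control array only and at least 2.61-fold and 2.27-fold lower. Another 4 members were above background on the LPS array only. These were Saa3 and S100a8, given above, and Orm1 and Ltf, chosen after their values were seen, at least 8.94-fold and 8.18-fold higher. A further 17 members were above background on neither array.

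Interferon-stimulated genes stood close to the middle of the array. Of 39 measured members, 1 was at least 2-fold higher, 2 were 2-fold lower and 36 were neither, with a median of 0.06. Zbp1, a sensor of nucleic acids, was at 1.57 ± 0.07 and Parp14 at 0.87 ± 0.05. Gbp2 was at -2.50 ± 0.20 on 1 dim probe and at -1.17 with normexp, and Usp18 at -1.25 ± 0.07.

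Of 26 measured mucin and goblet cell genes, 2 were at least 2-fold higher, 1 was lower and 23 were neither, with a median of -0.04. Agr2, chosen after its value was seen, was above background on the control array only and at least 2.07-fold lower. Clca3b stood at 2.90 ± 0.05, the transmembrane mucin gene Muc1 at 1.19 ± 0.07 and Spdef, which encodes a goblet cell transcription factor, at -1.96 ± 0.20 (-1.29 with normexp). Of 34 junction genes, 2 were at least 2-fold higher, none was lower and 32 were neither, with a median of -0.04. Tjp3, a tight junction scaffold gene, was at 1.69 ± 0.03 and the adhesion gene Epcam at -0.56 ± 0.03. None of 48 cell cycle genes reached 2-fold either way, and their median was -0.09, with 9 above 0.

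Among the other lists, glycolysis and hypoxia genes were above 0 for 33 of 33 measured members, with a median of 0.41 and 2 members at least 2-fold higher. Pfkfb3, which encodes an enzyme that drives glycolysis, was at 1.25 ± 0.03 and the oxidoreductase gene Ero1a at 1.05 ± 0.07, and at 0.95 with normexp. A further member, Slc2a3, chosen after its value was seen, was above background on the control array only and at least 2.04-fold lower. Antigen processing and MHC class I genes were above 0 for 13 of 13 measured members, with a median of 0.28 and H2-K1 highest at 0.58 ± 0.03. Of its members above background on 1 array, chosen after their values were seen, H2-Q1 was at least 1.24-fold lower on the LPS array, and Tap1 and Psmb9 at least 1.40-fold and 2.18-fold higher. Epithelial markers were below 0 for all but 1 of 17, with a median of -0.19, Krt20 at -0.92 ± 0.20 and Elf3 at 0.70 ± 0.05. Absorptive colonocyte genes had a median of -0.19, with 2 of 18 at least 2-fold higher and 2 lower, including Cdhr5 at -1.33 ± 0.20. With normexp neither lower gene stayed past 2-fold, and Cdhr5 was at -0.47. Among the brighter genes alone the median of this list was 0.18, above the random range instead of below it.

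Matrix protease and mesenchymal transition genes had medians of 0.26 and 0.22, and the second median was -0.01 among the brighter genes. Immediate early genes had a median of -0.18, with Ier3 at 1.35 ± 0.03 and Klf2 at -1.02 ± 0.07, and replication-dependent histone genes one of -0.21. Stress and lipid lists had small medians, at 0.12 for the unfolded protein response, 0.06 for oxidative stress, 0.13 for sterol synthesis and 0.07 for fatty acid metabolism. Notch and TGF-beta pathway genes had medians of 0.10 and 0.11, and the mean of the Notch genes was -0.087. Of the MHC class II list only 4 genes were measured, with a median of 0.14 and no percentile.

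Several lists lay within the range of random lists. Their medians were -0.08 for stem cell and WNT targets, -0.04 for enteroendocrine and tuft cells, -0.02 for apoptosis and p53 targets, -0.02 for the EGF family, 0.07 for prostanoid genes, 0.02 for ribosomal proteins, -0.03 for mitochondrial respiration, 0.05 for heat shock and 0.03 for housekeeping genes. Those of the apoptosis, EGF family, ribosomal protein, housekeeping, lymphocyte, and enteroendocrine and tuft cell lists changed sign under at least 1 other scaling.

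Of 19 macrophage markers 7 were measured, with a median of 0.23 and Aif1 and Cd14 at least 2-fold higher. Another 7, among them the abundant macrophage transcripts Lyz2, Tyrobp and Laptm5, were not well above background on either array. Adgre1, Mrc1 and Mpeg1 were above background on the LPS array only, at least 1.96-fold, 1.83-fold and 1.52-fold higher, and Itgax and Ptprc, the pan-leukocyte marker gene, on the control array only, at least 1.92-fold and 3.03-fold lower. The genes named here beyond Aif1 and Cd14 were chosen after their values were seen. The medians were -0.01 for 6 measured lymphocyte markers, 0.33 for 5 fibroblast markers and 0.05 for 5 endothelial markers.

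Each list's median was set against 10000 random lists of the same size matched on brightness. Of 36 lists, 18 lay above the central 95%. Another 5 lay below, those of cell cycle, immediate early, colonocyte, histone and epithelial genes. Several lists on either side lost their place under some alternatives, as given below. By chance 1.8 lists would lie outside if genes were independent. Genes of one pathway vary together, so the percentiles describe these arrays only. Among the 9 main lists, those of Toll-like receptor signalling, NF-kB, chemokines, cytokines, interferon-stimulated genes and antimicrobial genes lay above, cell cycle genes lay below, and mucin and junction genes within. The percentile of the interferon list was 99.5 with the median and 88.7 with the mean of its members.

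**Figure D2:**
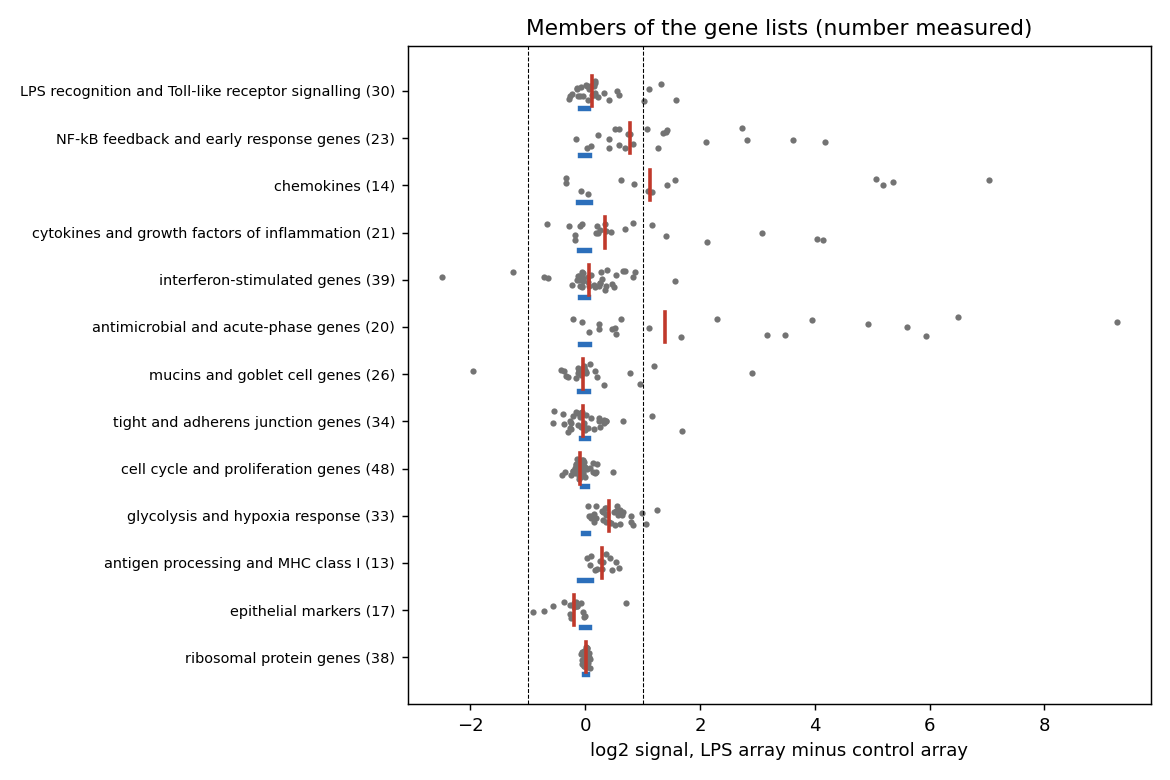
Each grey point is a measured member of a list, placed by its log2 difference, LPS minus control, with the number measured in brackets; red bars are list medians, blue bars the central 95% of 10000 random lists, and dashed lines 2-fold. The medians of antimicrobial and acute-phase genes (1.40), chemokines (1.13) and NF-kB genes (0.78) stand farthest above the blue bars.

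Along chromosome 3, some genes of the epidermal differentiation complex, a cluster that encodes proteins of the skin barrier, were higher. This region was singled out after the values were seen. Of 36 genes measured from the S100a9 probe to the S100a11 probe, 13 (36.1%) were at least 2-fold higher, 23 were under 2-fold and none was 2-fold lower. Some of the 36 had only a clone or probe name. Over all measured genes with a position, 1.5% were at least 2-fold higher. The stretch starts at a higher gene, S100a9, so its share is not that of the whole complex. Among the higher genes were Pglyrp3 at 3.92 ± 0.20, Lor at 1.85 ± 0.03 and Lce1g at 2.71 ± 0.07. Sprr2a2, a very bright member, stood at 0.05, and Sprr2a1, above background on the control array only, was at least 2.27-fold lower.

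**Figure D3:**
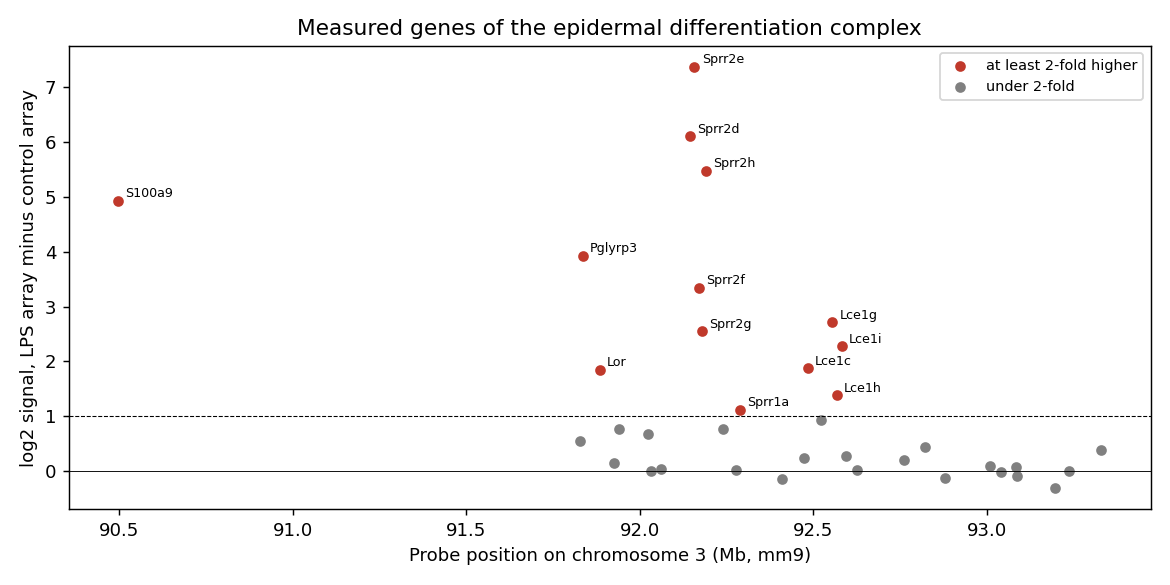
Each point is a measured gene, placed by its probe's position on chromosome 3 (Mb, mm9) and its log2 difference, LPS minus control; red points are at least 2-fold higher and the dashed line marks 2-fold. The 13 red points reach from 1.12 (Sprr1a) to 7.37 (Sprr2e), and the other 23 genes lie between -0.31 and 0.93.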

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

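The block correction and the random lists matched on GC were chosen after seeing the data. The scalings and the median over probes moved the median of all measured genes by less than 0.1. The causes of the changes below were not tested, except that a filter sets which genes are counted. Normexp gave 170 higher and 37 lower genes at 2-fold, 451 and 201 at 1.5-fold, and 46 and 1 at 4-fold. The brighter genes alone gave 94 and 15, 221 and 75, and 27 and 0. Without the background filter these were 1362 and 1178, 2559 and 2459, and 476 and 331, so 53.6% of the 2-fold genes were higher. All other alternatives stayed within 1.5 times of each count. With the looser flag for signal above background, 1257 genes were above it on the LPS array only and 1544 on the control array only.

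Some lists crossed the edge of the random range, with the list's value under that setting in brackets. Fatty acid genes came within it with quantile normalization (0.029), loess (0.072), no background filter (0.064) and the mean (0.11). Oxidative stress genes did so with loess (0.032) and the mean (0.13). The mean also brought in interferon-stimulated genes (0.073), the unfolded protein response (0.047), sterol genes (0.15), TGF-beta genes (0.13) and fibroblast markers (0.38), and put stem cell genes (-0.11) and mitochondrial respiration genes (-0.028) below it. Among the brighter genes, immediate early genes (-0.083) and Notch genes (0.13) came within it. Without the background filter, Notch genes (0.10) and macrophage markers (0.12) came within it and stem cell genes (-0.061) fell below. The median over probes put junction genes (-0.081) below.

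Some medians changed sign. Absorptive colonocyte genes stood at 0.18 among the brighter genes, above the random range instead of below it, 0.090 without the background filter and 0.062 with the mean. Mesenchymal genes stood at -0.0051 among the brighter genes, and Notch genes at -0.087 with the mean. The lists of Toll-like receptor, NF-kB, chemokine, cytokine, antimicrobial and cell cycle genes kept their side of the random range under all 15 alternatives. The median of antimicrobial genes was 0.38 without the background filter and 3.32 among the brighter genes.

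Of 56 named genes at least 2-fold different and measured on both arrays, none changed sign, and normexp left 11 under 2-fold: Klf2, Areg, Acta2, Apcdd1, Dll4, Nectin1, Slc7a11, Ero1a (0.95), Cdhr5 (-0.47), Slc9a3 (-0.76) and Cd14. Of the others, normexp moved Zc3h12a to 2.81, Tnf to 3.10, Csf3 to 3.39, Lcn2 to 8.58, Spdef to -1.29, Gbp2 to -1.17 and Aif1 to 1.32. Klf2, Areg and Apcdd1 were also under 2-fold with loess and with spike-in scaling, and the median over probes put Scgb2b20 at -0.77 and C3 at 5.67. Cd14 lies at the edge of 2-fold, at 0.996 with quantile normalization. C3 was at 4.67 with normexp and 4.84 with the floored signal. Log2 bounds of genes above background on 1 array were smaller with normexp, at 9.81 for Saa3, 2.48 for S100a8, 1.90 for Slc26a4 and 2.05 for Olfr472. No paired analysis was possible because each group has 1 array, and for that reason no slide block and no left-out replicate were run. Signal over background limits the lower genes most, since 101 of 116 were dim, against 203 of 297 higher genes.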

Other observations

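The genes in this paragraph were chosen after their values were seen. Complement genes, C3 included, were at least 2-fold higher on the LPS array for 7 of 11 measured members and lower for none, a count that was 7 under each other scaling. Cfb, which encodes factor B of the alternative pathway, was 11.2-fold higher, and the classical pathway protease genes C1ra, C1s1 and C1s2 were 7.52-fold, 5.52-fold and 5.68-fold higher. C1s1 and C1s2 had nearly the same log2 signal, at 1.28 and 1.23 on the control array and 3.74 each on the LPS array. Probes of related complement genes were not set against each other's transcripts. Shared signal is thus not excluded, and the 7 may not be separate measurements. C1rl, C4b, Cd55 and Serping1 were under 2-fold. Of 4 measured genes of the calcium-activated chloride channel regulator family, Clca3a1, Clca3a2 and Clca3b were 5.37-fold, 6.18-fold and 7.45-fold higher, while the much brighter Clca1 stood at a log2 difference of -0.0030 on its brightest probe and as low as -0.74 on another.

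Cytokine receptor, transcription factor and related genes of the acute-phase response were mixed. Osmr, which encodes the oncostatin M receptor, was 4.97-fold higher, Cebpd 5.34-fold higher and Lrg1 21.7-fold higher. Il6ra, Il6st, Stat3 and the feedback gene Socs3 were under 2-fold, and Socs1 was at -0.68. These genes, too, were chosen after their values were seen.

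Of the tests below, those on GC content, on the 2 cultures and on the scaling factor were chosen only after the result was seen. The others were set before their own results, but on patterns already seen in the values. Some genes of the epidermal differentiation complex, a cluster of skin barrier genes on chromosome 3, were higher, and the region was singled out after the values were seen. Between probe starts 90496573 and 93330022 (mm9), 13 of 36 measured genes were at least 2-fold higher and none was lower, while Sprr2a1, above background on the control array only, was at least 2.27-fold lower. The count was 12 to 14 under the other scalings. Cross-hybridisation between relatives stays open. Outside the Sprr2 and Lce families, 5 higher members had a probe under 70% identical to every other higher member's probe. These count S100a8 by its bound, though its probe starts at 90473778, before the stretch above. Within those families, 0 of 9 higher members had a probe 90% or more identical. The thresholds set beforehand would have excluded cross-hybridisation, but were wrong by design, because a probe binds transcripts and no transcript sequences were compared here.

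Glycolysis and hypoxia genes were above 0 for 33 of 33 measured members, while Slc2a3, above background on the control array only and chosen after its value was seen, was at least 2.04-fold lower. A brightness-dependent difference between the arrays was argued against by the medians over deciles of brightness, which ran only from -0.0612 to 0.0036. After intensity-dependent loess the list's median was 0.41, still above its random range. So small a trend made that outcome near certain, so it adds little. Probe GC content was argued against by the list's percentile of 100 among random lists matched on brightness and GC. A difference between the 2 cultures other than LPS, such as cell density or medium, cannot be told apart from LPS, because there was 1 sample per group. A response to LPS may account for the pattern, and that was not tested.

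Few interferon-stimulated genes were at least 2-fold higher, 1 of 39 measured, beside 10 of 23 NF-kB genes. Over all measured genes 297 of 20380 were, so the count is low beside the NF-kB list and not beside the whole array. Of the 39 measured interferon-stimulated genes, 19 were at or above the median brightness, and 0 of these were at least 2-fold higher. Low brightness does not apply to these 19, but they were picked as bright. Only 94 of all measured genes that bright were at least 2-fold higher, so 0 of 19 carries little weight. The bright NF-kB genes were not counted apart, so brightness as a reason for the contrast is undecided. The count of 19 alone decides nothing, because the median is that of the measured genes. Low brightness stays open for the dimmer members, with 12 on the list above background on neither array and 3 on the control array only. One wrong scaling factor between the arrays is argued against. The fifth highest member lacks 0.34 to 2-fold, and the lowest of 7 spike-in probes was at -0.0704 and the highest at 0.0735. Ifnb1, the interferon beta gene, chosen after its value was seen, was not well above background on either array. The difference between the 2 lists was not tested, and 24 h was the only time measured. No biological explanation was tested.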
